A study of Mus musculus with 18 samples.

How the data were processed

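RNA of mouse nasal mucosa was sequenced after poly(A) selection in 18 libraries, 6 in each of the groups CON, CRS and C10, per the labels. The kit named there, VAHTS Universal V6, is not stated to keep the strand. The deposited count table holds raw read counts per gene, as whole numbers, with 1 column per library and 54532 genes; the submitters' processing notes give the genome build mm10, and the aligner, the counting tool and the annotation release are not given in the sources used here. The deposited FPKM table was made by the authors from the same counts: within each column the ratio of count to gene length and FPKM is 1 constant, which implies library sizes of 0.877 to 1.081 times the column totals, within 0.015 of the TMM factors of edgeR. All columns were matched to a library, and 0 were left over. The FPKM values were used only as an alternative.

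Differential expression was computed from the counts in R 4.3.3 with edgeR 4.0.16: genes with low counts were removed with filterByExpr by group (18291 of 54532 kept), TMM factors were computed, and quasi-likelihood F-tests were run on all 18 libraries with 1 mean per group. P-values are two-sided, and Benjamini-Hochberg adjusted values under 0.05 count as called. The biological coefficient of variation was 0.264. CPM values use TMM-scaled library sizes, and the SE of a log2 fold change is its size over the square root of F. The 45 gene lists, of which 43 had at least 3 measured members, were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) at a preset correlation of 0.01, with an estimated correlation and with fry beside it, each adjusted over the 43 lists of a comparison. The lists, the tests, the alternatives and the rule for named genes were fixed before the data were examined, except where the text says otherwise.

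Genes were named by a rule. Per comparison it took the 8 largest rises and falls among called genes with a mean of at least 1 CPM and all 6 libraries of a group beyond the other group's median, leaving out gene models without a proper symbol, odorant and vomeronasal receptors and immune receptor segments; where none passed, it took the 4 of smallest p in that direction, given as values. It also took the 3 members of smallest p from each list that passed, 15 fixed genes, and genes called with opposite sign in CRS against CON and C10 against CRS. Of the 127 genes so named, 40 overlap another gene of the table and 16 a protein-coding one, and without strand such counts cannot be separated.

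Alternatives were other size factors (RLE), no filter, a stricter filter (1 CPM in 6 libraries), the replicate number as a block, only the 2 groups compared, the mean level of mature olfactory neuron genes as a covariate, DESeq2 1.42.0, limma-voom with quality weights, limma on log2 of FPKM plus 1 or 0.1, a 2-fold minimum and leaving out each library in turn. The shared CRS libraries were handled by simulating unchanged groups and by splitting them. On simulated counts of 18291 genes with 100 genes changed 1.5-fold and 100 changed 2-fold, edgeR recovered 34 and 67 for CRS against CON with 7 false calls, 37 and 76 for C10 against CRS with 6, and 34 and 72 for C10 against CON with 3. A value of 3 counts, taken as the floor, equals 0.163 to 0.189 CPM and covers counting error only. Among 153 pairs of libraries the lowest chi-square per degree of freedom was 14.5, so no pair is a repeat count of 1 library.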

Results

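Nasal mucosa of mice was profiled by RNA sequencing in 18 libraries, 6 in each of 3 groups. The CRS group models chronic rhinosinusitis, a lasting inflammation of the lining of the nose and sinuses, with papain, a plant protease: 20 µg in 20 µL was given into the nose on days 0 to 2 and 7 to 11. The C10 group is taken to hold mice given papain, because the protocol gives the compound to CRS mice, and, once daily for 10 days from the opening papain dose, the compound C10 at 10 mg/mL and 10 µL per side. The series title describes the compound as an inhibitor of APE1, a DNA repair enzyme that also acts on the redox state of transcription factors. The labels do not say what the control group (CON) received, nor the age, strain, sex or hour of collection, nor whether each library came from a separate mouse, so p-values measure the spread between these libraries. Totals per library ran from 16510920 to 18433866 counts in CON, from 16531779 to 17523368 in CRS and from 15883573 to 18128186 in C10 (n = 6 each).

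Libraries within a group differed widely. The first principal component held 32.7% of the variance and did not follow the groups: CRS 2 lay at -80.9, CRS 5 at -59.1 and CRS 1 at 64.6, against -26.7 to 49.5 in CON and -32 to 31.8 in C10. The genes of nasal glands, which make odorant-binding proteins and lipocalins, had a mean log2 CPM of 8.64 in CRS 1 against 11.22 to 12.57 in the other CRS libraries. Interferon response genes had a mean of 2.44 in CRS 2 against 4.44 to 4.88 in the other CRS libraries. Ddx3y, a gene of the Y chromosome, was present at 49.0 to 67.1 CPM in all 18 libraries, and Xist, which silences the X chromosome in females, had at most 5 counts in a library.

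The comparison of CRS with CON asks what papain treatment changed in the mucosa. Ppargc1a, a coactivator of genes for mitochondria, rose 1.78-fold in CRS, from 35.6 ± 6.14 to 63.5 ± 10.0 CPM (SD, n = 6 each; log2 fold change 0.83 ± 0.12 SE; edgeR adjusted p = 0.018), and all 6 CRS libraries lay above the CON median. Chil4, a chitinase-like protein of type 2 airway inflammation, averaged 489.7 ± 769 CPM in CRS and 4.84 ± 8.49 CPM in CON; with a log2 fold change of 6.65 ± 1.49 it did not pass (edgeR adjusted p = 0.206), and its lowest CRS value (17.4 CPM, CRS 1) lay below the highest CON value (22.0 CPM, CON 6). The genes with the smallest p below 0 did not pass either: Prx (-0.94 ± 0.19), Nrarp (-0.83 ± 0.18), Arhgap20 (-1.03 ± 0.22) and Tmem100 (-0.72 ± 0.15), each with an edgeR adjusted p of 0.206; Prx is a protein of myelinating Schwann cells and Nrarp a target of Notch signalling. In the mm10 build the files place Ppargc1a (ENSMUSG00000029167) on chromosome 5 from 51454250 to 51567726 and Chil4 (ENSMUSG00000063779) on chromosome 3 from 106201490 to 106219507.

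Of 18291 genes tested, edgeR called 1 higher and 0 lower, while 2569 had an unadjusted p under 0.05 against a mean of 915 by chance. Genes move together across libraries, which spreads that chance number widely, so the excess alone is no evidence of a group effect. DESeq2 called 129 higher and 50 lower, and limma-voom with quality weights 395 and 545. The count rested on CRS 1: without it edgeR called 398 genes higher and 596 lower of 18452 tested, with Chil4 at 6.90 ± 1.43 (edgeR adjusted p = 0.0192). This fit was singled out after its count, the highest with 1 library left out, had been seen. It called 31 of the 59 genes named in this comparison, a high share favoured in advance, because many were named for a small p in the same libraries. The call of Ppargc1a ended, at 0 genes called in all, without CON 1, 4 or 5, CRS 4 or CRS 6 (edgeR adjusted p up to 0.0921), with the 2 groups alone (edgeR adjusted p = 0.198) and with the replicate block (edgeR adjusted p = 0.0692). Without CON 6 or C10 1, 2 genes were called. Chil4 passed in 2 of the 29 alternative fits, the fit without CRS 1 among them.

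Genes of energy metabolism and translation moved up together in CRS. The mitochondrially encoded genes, which code for subunits of the respiratory chain, rose as a group, with 12 of 13 measured members above 0 (median log2 fold change 0.72, camera adjusted p = 2.31e-07, and adjusted p = 0.559 with an estimated correlation). mt-Nd1 (0.74 ± 0.19), mt-Nd2 (0.74 ± 0.19) and mt-Nd3 (0.77 ± 0.20) had the smallest p in that direction. Of these 13 genes, 9 rose when adjusted over the list alone, against 0 over all genes tested. Cytosolic ribosomal protein genes rose as a group, with 81 of 85 measured members above 0 (median log2 fold change 0.30, camera adjusted p = 3.8e-18, and adjusted p = 0.559 with an estimated correlation). Rplp2 (0.63 ± 0.16), Rpl30 (0.73 ± 0.19) and Rpl21 (0.94 ± 0.25) had the smallest p in that direction. Of these 85 genes, 34 rose when adjusted over the list alone, against 0 over all genes tested. Ribosomal protein genes have many near-identical pseudogenes, so their counts are uncertain. Genes of hypoxia and glycolysis rose as a group, with 13 of 18 measured members above 0 (median log2 fold change 0.17, camera adjusted p = 0.0425, and adjusted p = 0.559 with an estimated correlation). Aldoa (0.30 ± 0.14), Tpi1 (0.18 ± 0.08) and Pgk1 (0.18 ± 0.09) had the smallest p in that direction. Of these 18 genes, 0 passed, adjusted over the list alone or over all genes tested. The circadian clock genes rose as a group, with 11 of 14 measured members above 0 (median log2 fold change 0.15, camera adjusted p = 0.0152, and adjusted p = 0.559 with an estimated correlation). Bhlhe41 (0.83 ± 0.14), Nr1d2 (0.28 ± 0.10) and Dbp (0.49 ± 0.18) had the smallest p in that direction. Of these 14 genes, 1 rose when adjusted over the list alone, against 0 over all genes tested. Odorant receptor genes, each used by a small share of olfactory neurons, rose as a group, with 467 of 635 measured members above 0 (median log2 fold change 0.20, camera adjusted p = 0.000154, and adjusted p = 0.712 with an estimated correlation). Olfr972 (0.81 ± 0.25), Olfr1320 (1.05 ± 0.37) and Olfr1431 (1.53 ± 0.54) had the smallest p in that direction. Of these 635 genes, 0 passed, adjusted over the list alone or over all genes tested. A camera call ended when 1 library was left out for hypoxia and glycolysis without CON 1, 4 or 6 or CRS 1, 3 or 5 (adjusted p = 0.0556 to 0.143), circadian clock without CRS 2 (adjusted p = 0.0526) and odorant receptors without CON 5 or CRS 2 (adjusted p = 0.228 to 0.341). With the mean level of mature olfactory neuron genes as a covariate the camera adjusted p of the odorant receptors was 0.608. Without CRS 2 and 5, which lay apart on the first component, the median of the odorant receptors turned to -0.064 (camera adjusted p = 0.96), and the clock list did not pass (camera adjusted p = 0.25). The median moved by over 1.5 times, the camera call kept, for circadian clock (0.10 with the olfactory covariate, 0.10 without CRS 5), odorant receptors (0.34 without CON 6, 0.33 without CRS 1, 0.13 without CRS 5), mitochondrially encoded genes (0.46 without CRS 5, 0.44 without CRS 2 and 5 together) and cytosolic ribosomal proteins (0.19 without CRS 4).

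Genes of connective tissue and vessels moved down together in CRS. Genes of matrix remodelling fell as a group, with 18 of 20 measured members below 0 (median log2 fold change -0.61, camera adjusted p = 9.72e-06, and adjusted p = 0.559 with an estimated correlation). Ctgf (-0.83 ± 0.24), Acta2 (-0.51 ± 0.15) and Mmp2 (-0.60 ± 0.22) had the smallest p in that direction. Of these 20 genes, 2 fell when adjusted over the list alone, against 0 over all genes tested. Fibroblast markers fell as a group, with 8 of 8 measured members below 0 (median log2 fold change -0.52, camera adjusted p = 8.06e-05, and adjusted p = 0.559 with an estimated correlation). Pdgfrb (-0.54 ± 0.19), Col6a2 (-0.65 ± 0.24) and Col6a1 (-0.61 ± 0.23) had the smallest p in that direction. Of these 8 genes, 3 fell when adjusted over the list alone, against 0 over all genes tested. Endothelial markers, among them the receptors of vessel growth Kdr and Tek, fell as a group, with 11 of 11 measured members below 0 (median log2 fold change -0.48, camera adjusted p = 8.06e-05, and adjusted p = 0.559 with an estimated correlation). Tek (-0.53 ± 0.20), Kdr (-0.55 ± 0.24) and Cdh5 (-0.58 ± 0.28) had the smallest p in that direction. Of these 11 genes, 0 passed, adjusted over the list alone or over all genes tested. Red blood cell genes fell as a group, with 7 of 7 measured members below 0 (median log2 fold change -1.30, camera adjusted p = 0.00424, and adjusted p = 0.559 with an estimated correlation). Alas2 (-1.85 ± 0.49), Hba-a1 (-1.41 ± 0.50) and Slc4a1 (-2.80 ± 1.19) had the smallest p in that direction. Of these 7 genes, 2 fell when adjusted over the list alone, against 0 over all genes tested. Immediate early and heat shock genes, which respond within minutes to handling and stress, fell as a group, with 15 of 16 measured members below 0 (median log2 fold change -0.40, camera adjusted p = 8.06e-05, and adjusted p = 0.559 with an estimated correlation). Hspa1b (-0.48 ± 0.13), Hspa1a (-0.38 ± 0.10) and Egr1 (-0.88 ± 0.29) had the smallest p in that direction. Of these 16 genes, 3 fell when adjusted over the list alone, against 0 over all genes tested. Hspa1a and Hspa1b are near-identical copies, as are the alpha globin genes, and Alas2 overlaps Apex2, so each is uncertain. The median moved by over 1.5 times, the camera call kept, for matrix remodelling (-0.40 with the olfactory covariate, -0.33 without CON 3, -0.34 without CRS 2 and 5 together), fibroblasts (-0.85 without CRS 1, -0.32 without CRS 2 and 5 together), endothelium (-0.22 without CRS 2 and 5 together) and erythroid cells (-0.77 with the olfactory covariate, -0.72 without CON 3).

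6 more lists, of inflammation, myeloid cells and the airway lining, also stood lower in CRS. Genes of NF-kB and acute inflammation fell as a group, with 21 of 22 measured members below 0 (median log2 fold change -0.56, camera adjusted p = 0.000115, and adjusted p = 0.635 with an estimated correlation). Ptgs2 (-1.90 ± 0.50), Cxcl1 (-1.19 ± 0.42) and Il6 (-1.96 ± 0.74) had the smallest p in that direction. Of these 22 genes, 1 fell when adjusted over the list alone, against 0 over all genes tested. NADPH oxidases and other producers of reactive oxygen fell as a group, with 11 of 12 measured members below 0 (median log2 fold change -0.28, camera adjusted p = 0.0265, and adjusted p = 0.673 with an estimated correlation). Nox4 (-0.71 ± 0.29), Xdh (-0.24 ± 0.11) and Duox2 (-0.61 ± 0.54) had the smallest p in that direction. Of these 12 genes, 0 passed, adjusted over the list alone or over all genes tested. Neutrophil markers fell as a group, with 9 of 10 measured members below 0 (median log2 fold change -0.58, camera adjusted p = 0.0047, and adjusted p = 0.635 with an estimated correlation). Mmp9 (-1.14 ± 0.42), Cxcr2 (-0.86 ± 0.48) and Csf3r (-0.68 ± 0.45) had the smallest p in that direction. Of these 10 genes, 0 passed, adjusted over the list alone or over all genes tested. Markers of macrophages and dendritic cells fell as a group, with 14 of 14 measured members below 0 (median log2 fold change -0.40, camera adjusted p = 0.00162, and adjusted p = 0.635 with an estimated correlation). Cd163 (-1.11 ± 0.31), Ccr2 (-0.69 ± 0.34) and Csf1r (-0.59 ± 0.38) had the smallest p in that direction. Of these 14 genes, 1 fell when adjusted over the list alone, against 0 over all genes tested. Mucins and secretoglobins of airway mucus fell as a group, with 8 of 10 measured members below 0 (median log2 fold change -0.41, camera adjusted p = 0.0359, and adjusted p = 0.559 with an estimated correlation). Bpifb1 (-0.56 ± 0.24), Muc20 (-0.40 ± 0.19) and Muc5ac (-0.83 ± 0.43) had the smallest p in that direction. Of these 10 genes, 0 passed, adjusted over the list alone or over all genes tested. Ciliated cell markers fell as a group, with 14 of 18 measured members below 0 (median log2 fold change -0.14, camera adjusted p = 0.0272, and adjusted p = 0.673 with an estimated correlation). Foxj1 (-0.43 ± 0.14), Spag17 (-0.73 ± 0.26) and Rsph4a (-0.37 ± 0.15) had the smallest p in that direction. Of these 18 genes, 0 passed, adjusted over the list alone or over all genes tested. With the mean level of mature olfactory neuron genes as a covariate, the camera adjusted p was 0.206 for the NADPH oxidases and 0.0549 for the mucins. Without CRS 2 and 5 the camera adjusted p was 0.25 for NF-kB (median -0.29), 0.932 for the NADPH oxidases (-0.023), 0.432 for the neutrophils (-0.35), 0.528 for the macrophages and dendritic cells (-0.043) and 0.0879 for the mucins (-0.28). A camera call ended when 1 library was left out for NADPH oxidases and ROS production without CON 3, 4 or 5 or CRS 2 (adjusted p = 0.0564 to 0.289), neutrophils without CRS 2 (adjusted p = 0.0624), macrophages and dendritic cells without CRS 2 (adjusted p = 0.0567), mucins and secretoglobins without CON 3 or 6 or CRS 1, 2 or 4 (adjusted p = 0.0526 to 0.101) and ciliated cells without CON 1, 2 or 3 or CRS 1 or 3 (adjusted p = 0.0515 to 0.226). The median moved by over 1.5 times, the camera call kept, for NF-kB and acute inflammation (-0.16 without CON 3, -0.98 without CRS 1, -0.35 without CRS 2), NADPH oxidases and ROS production (-0.50 without CRS 1), neutrophils (-0.88 with the replicate block, -0.26 without CON 3, -1.28 without CRS 1), macrophages and dendritic cells (-0.25 without CON 4, -0.23 without CON 5, -0.70 without CRS 1, -0.24 without CRS 5) and ciliated cells (-0.22 without CRS 2 and 5 together).

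Type 2 inflammation is the allergy-like response that papain is known to raise in airways, and of its cytokines Il5, Il13, Il25 and Tslp were near the limit of detection. Il5 had 3 counts in CON, 13 in CRS and 2 in C10 over all 6 libraries of a group, and Il13 had 1, 14 and 4, of which 12 were in CRS 2. Il25, a cytokine of tuft cells, had 25, 41 and 46, Tslp, an epithelial alarm cytokine, 29, 29 and 23, and the eosinophil peroxidase Epx 59, 6 and 24, with all 59 of CON in CON 5. Clca1, made by goblet cells, had 6, 52 and 272 counts, of which 219 were in C10 4. Retnlb had 0 counts in all 18 libraries, where 3 counts equal 0.163 to 0.189 CPM. Among the fixed genes that were tested, Il4 (-0.09 ± 0.24), Il33 (-0.22 ± 0.09), Il6 (-1.96 ± 0.74), Tnf (-0.77 ± 0.41), Il1b (-1.21 ± 0.56) and Muc5ac (-0.83 ± 0.43) did not pass in CRS against CON (edgeR adjusted p from 0.269 to 0.883).

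**Figure D1:**
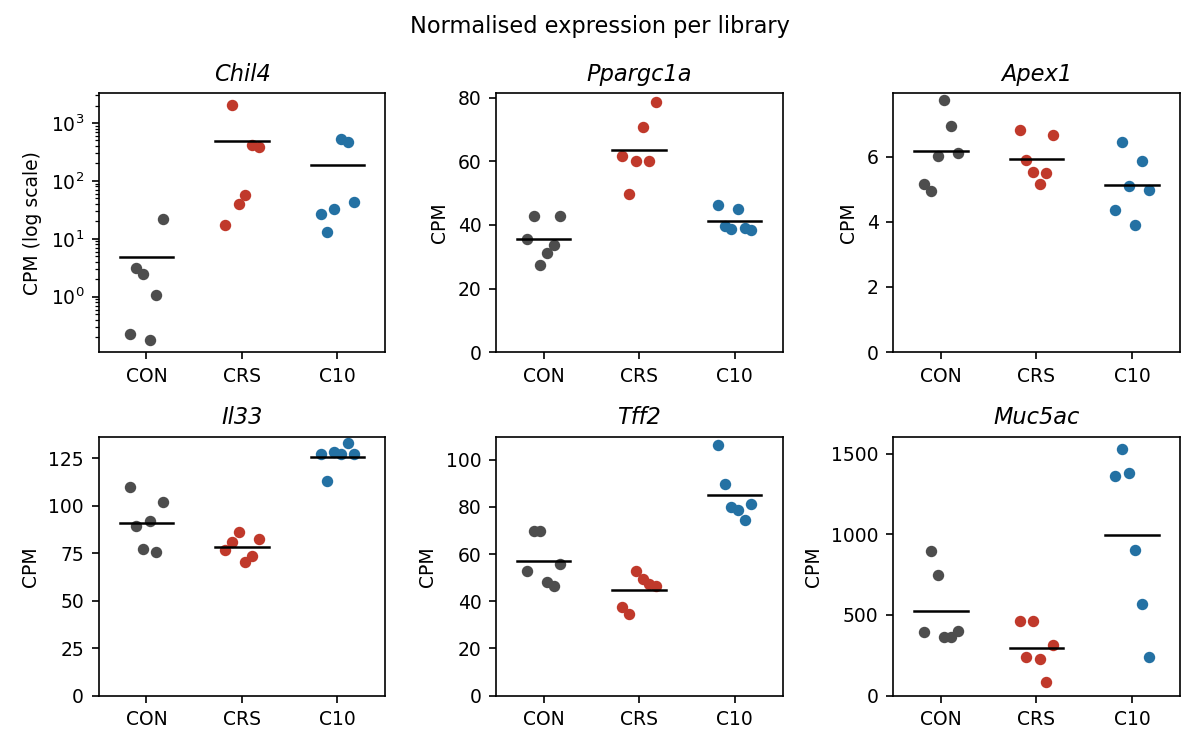
Normalised expression (CPM) of 6 genes in each of the 18 libraries; points are libraries, the line is the group mean, and the axis of Chil4 is logarithmic. Ppargc1a averaged 63.5 CPM in CRS against 35.6 CPM in CON, and Chil4 spread from 17.4 to 2020 CPM within CRS.

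The comparison of C10 with CRS asks what differed between papain-treated mice with and without the compound. No vehicle dose is recorded here for CRS, so the compound cannot be told apart from the added dosing itself. The hour of collection is not given either, so a difference in hour between the groups cannot be told apart from the compound. Gpnmb, a membrane glycoprotein of lysosome-rich cells such as macrophages and osteoclasts, fell 9.82-fold, from 374 ± 265 to 38.1 ± 24.8 CPM (SD, n = 6 each; log2 fold change -3.30 ± 0.56 SE; edgeR adjusted p = 0.0239). Il33, an alarm cytokine held in the nuclei of epithelial and stromal cells, rose 1.61-fold, from 78.3 ± 5.76 to 126 ± 6.75 CPM (log2 fold change 0.68 ± 0.09; edgeR adjusted p = 0.00233). Tff2 (0.93 ± 0.13), a trefoil factor of mucus, and Galnt15 (0.80 ± 0.12), of the family that starts O-linked glycosylation, also rose. Uap1l1 (-1.04 ± 0.12), Dpp7 (-0.99 ± 0.15), Cd63 (-0.81 ± 0.13), Flcn (-0.70 ± 0.09) and Fuca2 (-0.52 ± 0.07) fell, of which Dpp7 is a peptidase of vesicles, Cd63 a tetraspanin of lysosomes and Flcn a regulator of nutrient signals at the lysosome. Vegfb (-0.54 ± 0.09), a growth factor of vessels, and Ppargc1a (-0.62 ± 0.12) fell as well. In each of these 11 genes all 6 libraries of one group lay beyond the median of the other.

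Of 18291 genes edgeR called 3 higher and 12 lower, with 2410 at an unadjusted p under 0.05 against a mean of 915 by chance. Because genes move together, that excess alone is no evidence of a group effect. The 12 include Cln8, a protein of the endoplasmic reticulum, and the proton pump genes Atp6ap2, Atp6v1c1 and Atp6v0c, which were picked out after their values were seen. Il33, Tff2, Uap1l1, Flcn, Fuca2 and Dpp7 passed in all 29 fits run, and of these 6 genes Uap1l1 alone also lay past a 2-fold minimum. With the 2 groups alone the call ended for Galnt15 (adjusted p = 0.0567), Gpnmb (adjusted p = 0.0581) and Ppargc1a (adjusted p = 0.0567), and with no filter on low counts for Vegfb (adjusted p = 0.0523), all by edgeR. The call also ended when 1 library was left out for Cd63 without C10 1, 2, 3 or 4 (adjusted p = 0.0588 to 0.0703), Gpnmb without CRS 3 or C10 2, 3, 4 or 6 (adjusted p = 0.0604 to 0.0797), Vegfb without CON 4, CRS 3, 5 or 6 or C10 1, 2, 3, 4 or 6 (adjusted p = 0.0508 to 0.107) and Ppargc1a without CON 1 or 4, CRS 3, 4, 5 or 6 or C10 1, 2, 3, 4, 5 or 6 (adjusted p = 0.0571 to 0.125), all by edgeR. The number called was 30 without CON 5, 29 without CRS 1, 81 without CRS 2, 25 without C10 5, 9 without C10 1 or 2, 7 without C10 3 and 8 without C10 4. With the olfactory covariate 387 genes were higher and 275 lower, by DESeq2 109 and 241, by limma-voom 227 and 321, and without CRS 2 and 5, which lay apart on the first component, 37 and 63. In mm10 the files place Gpnmb (ENSMUSG00000029816) on chromosome 6 from 49036546 to 49070929, Il33 (ENSMUSG00000024810) on chromosome 19 from 29925114 to 29960718 and Uap1l1 (ENSMUSG00000026956) on chromosome 2 from 25359889 to 25365682.

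Genes of mucus and cilia stood higher in C10 than in CRS. Mucins and secretoglobins rose as a group, with 9 of 10 measured members above 0 (median log2 fold change 0.51, camera adjusted p = 7.39e-05, and adjusted p = 0.461 with an estimated correlation). Muc5ac (1.74 ± 0.44), Bpifb1 (0.94 ± 0.24) and Muc20 (0.51 ± 0.19) had the smallest p in that direction. Of these 10 genes, 4 rose when adjusted over the list alone, against 0 over all genes tested. Muc5ac, the gel-forming mucin of goblet cells, averaged 997 ± 517 CPM in C10 against 298 ± 148 CPM in CRS, and did not pass (edgeR adjusted p = 0.109). Markers of ciliated cells rose as a group, with 16 of 18 measured members above 0 (median log2 fold change 0.26, camera adjusted p = 0.00295, and adjusted p = 0.911 with an estimated correlation). Spag17 (0.83 ± 0.26), Foxj1 (0.36 ± 0.14) and Rsph4a (0.36 ± 0.15) had the smallest p in that direction. Of these 18 genes, 0 passed, adjusted over the list alone or over all genes tested. Genes of immature olfactory neurons and their progenitors rose as a group, with 11 of 11 measured members above 0 (median log2 fold change 0.51, camera adjusted p = 6.33e-05, and adjusted p = 0.911 with an estimated correlation). Neurod1 (1.07 ± 0.29) and Neurog1 (1.05 ± 0.40) were among those of smallest p in that direction. Of these 11 genes, 2 rose when adjusted over the list alone, against 0 over all genes tested. The odorant receptors rose as a group, with 493 of 635 measured members above 0 (median log2 fold change 0.29, camera adjusted p = 4.28e-07, and adjusted p = 0.911 with an estimated correlation). Olfr988 (2.82 ± 0.56), Olfr508 (1.98 ± 0.44) and Olfr766-ps1 (1.35 ± 0.31) had the smallest p in that direction. Of these 635 genes, 0 passed, adjusted over the list alone or over all genes tested. Markers of neutrophils rose as a group, with 9 of 10 measured members above 0 (median log2 fold change 0.34, camera adjusted p = 0.0329, and adjusted p = 0.911 with an estimated correlation). Mmp9 (0.56 ± 0.42), Cxcr2 (0.62 ± 0.48) and S100a9 (0.35 ± 0.52) had the smallest p in that direction. Of these 10 genes, 0 passed, adjusted over the list alone or over all genes tested. Markers of T, NK and innate lymphoid cells rose as a group, with 12 of 15 measured members above 0 (median log2 fold change 0.34, camera adjusted p = 0.0452, and adjusted p = 0.92 with an estimated correlation). Cd8a (0.88 ± 0.75), Nkg7 (0.67 ± 0.57) and Trac (0.47 ± 0.53) had the smallest p in that direction. Of these 15 genes, 0 passed, adjusted over the list alone or over all genes tested. A camera call ended without 1 library for neutrophils without CRS 2 or 5 or C10 1 or 3 (adjusted p = 0.0511 to 0.31) and T, NK and innate lymphoid cells without CON 6, CRS 2 or 5 or C10 1 or 3 (adjusted p = 0.051 to 0.754). Without CRS 2 and 5 the direction turned, to a median of -0.18 for the neutrophils (camera adjusted p = 0.978) and -0.12 for the T, NK and innate lymphoid cells (camera adjusted p = 0.26). With the camera call kept, the median moved by over 1.5 times for immature olfactory neurons and progenitors (0.90 without CRS 2 and 5 together), odorant receptors (0.17 without CRS 1, 0.53 without CRS 2 and 5 together), neutrophils (0.60 with the replicate block, 0.70 with the olfactory covariate, 0.75 without CRS 1, 0.53 without CRS 4, 0.21 without CRS 6) and T, NK and innate lymphoid cells (0.52 with the replicate block, 0.60 with the olfactory covariate, 0.69 without CRS 1). Spag17 overlaps Wdr3, Muc20 overlaps Muc4 and Neurod1 overlaps Cerkl, which leaves these counts uncertain.

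Genes of glycolysis, mitochondria and translation stood lower in C10 than in CRS. Genes that respond to hypoxia or run glycolysis fell as a group, with 16 of 18 measured members below 0 (median log2 fold change -0.36, camera adjusted p = 1.89e-06, and adjusted p = 0.297 with an estimated correlation). Pgk1 (-0.38 ± 0.09), Vegfa (-0.46 ± 0.13) and Ldha (-0.47 ± 0.13) had the smallest p in that direction. Of these 18 genes, 7 fell when adjusted over the list alone, against 0 over all genes tested. By fry this list also passed (adjusted p = 0.0301). Genes of the mitochondrial genome fell as a group, with 13 of 13 measured members below 0 (median log2 fold change -0.65, camera adjusted p = 2.27e-08, and adjusted p = 0.548 with an estimated correlation). mt-Nd3 (-0.82 ± 0.20), mt-Nd1 (-0.65 ± 0.19) and mt-Nd2 (-0.66 ± 0.19) had the smallest p in that direction. Of these 13 genes, 12 fell when adjusted over the list alone, against 0 over all genes tested. Ribosomal protein genes fell as a group, with 84 of 85 measured members below 0 (median log2 fold change -0.25, camera adjusted p = 1.72e-13, and adjusted p = 0.911 with an estimated correlation). Rpl21 (-0.93 ± 0.25), Rplp2 (-0.57 ± 0.16) and Rps28 (-1.01 ± 0.32) had the smallest p in that direction. Of these 85 genes, 0 passed, adjusted over the list alone or over all genes tested. Keratins and other genes of squamous and basal cells fell as a group, with 14 of 16 measured members below 0 (median log2 fold change -0.36, camera adjusted p = 0.00333, and adjusted p = 0.911 with an estimated correlation). Ivl (-0.73 ± 0.25), Krt6a (-1.37 ± 0.57) and Krt5 (-0.30 ± 0.13) had the smallest p in that direction. Of these 16 genes, 0 passed, adjusted over the list alone or over all genes tested. That last camera call ended for squamous and basal keratinocyte without CRS 5 (adjusted p = 0.0722). It also ended without CRS 2 and 5 (camera adjusted p = 0.126). With the camera call kept, the median moved by over 1.5 times for mitochondrially encoded genes (-0.43 without CRS 5, -0.42 without CRS 2 and 5 together) and cytosolic ribosomal proteins (-0.11 without CRS 4, -0.38 without CRS 2 and 5 together). Of the fixed genes, Il4 (-0.08 ± 0.24), Il6 (-0.78 ± 0.81), Tnf (0.05 ± 0.41), Il1b (0.49 ± 0.55) and Chil4 (-1.40 ± 1.16) did not pass in C10 against CRS (edgeR adjusted p from 0.654 to 0.973). Chil4 averaged 185 ± 243 CPM in C10.

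The comparison of C10 with CON asks how far treated mice stood from controls. Gpnmb fell 12.7-fold, from 485 ± 333 to 38.1 ± 24.8 CPM (SD, n = 6 each; log2 fold change -3.67 ± 0.57 SE; edgeR adjusted p = 0.0122). Other genes fell with it: Trem2 (-1.75 ± 0.31), a lipid receptor of macrophages, Ctsd (-1.03 ± 0.18), the protease cathepsin D, and Hexa (-0.89 ± 0.16), a lysosomal hexosaminidase. Eln (-1.68 ± 0.27), the elastin of elastic fibres, Spon2 (-1.02 ± 0.16), a matrix protein, Slc25a34 (-1.49 ± 0.23), of the mitochondrial carrier family, and Nkain1 (-1.44 ± 0.26) fell too. Dbp, a transcription factor driven by the circadian clock, rose 2.44-fold, from 31 ± 5.82 to 75.6 ± 12.8 CPM (log2 fold change 1.29 ± 0.18; edgeR adjusted p = 0.0108). Neurod1 (1.80 ± 0.30), a transcription factor of neuron differentiation, Thegl (0.87 ± 0.16), Nr1d2 (0.52 ± 0.10), a repressor in the clock, Alas1 (0.50 ± 0.10), the rate-limiting enzyme of haem synthesis, and Il33 (0.47 ± 0.09) rose as well. In each of these 14 genes all 6 libraries of a group lay beyond the median of the other.

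Of 18291 genes edgeR called 8 higher and 21 lower, with 2401 at an unadjusted p under 0.05 against a mean of 915 by chance. Because genes move together, that excess alone is no evidence of a group effect. Among these 14 genes Dbp passed in all 29 fits run. With no filter on low counts the edgeR call ended for Alas1 (adjusted p = 0.0717), Il33 (adjusted p = 0.0687), Nkain1 (adjusted p = 0.0559), Nr1d2 (adjusted p = 0.0596) and Thegl (adjusted p = 0.0717), and by limma on log2 of FPKM plus 1 for Trem2 (adjusted p = 0.0527). On that scale the called log2 fold changes were smaller by over 1.5 times for Neurod1 (0.96), Nkain1 (-0.815), Slc25a34 (-0.77) and Thegl (0.58). The edgeR call ended when 1 library was left out for Gpnmb without C10 4 or 5 (adjusted p = 0.0514 to 0.0556), Trem2 without CON 2, 3, 4 or 5 or C10 1, 2, 3, 4, 5 or 6 (adjusted p = 0.0537 to 0.112), Eln without C10 4, 5 or 6 (adjusted p = 0.0512 to 0.0588), Slc25a34 without C10 4 (adjusted p = 0.0556), Nkain1 without CON 2, 3, 4 or 5 or C10 1, 2, 3, 4, 5 or 6 (adjusted p = 0.0524 to 0.106), Ctsd without CON 2, 3 or 4 or C10 1, 2, 4, 5 or 6 (adjusted p = 0.0537 to 0.108), Spon2 without C10 4 (adjusted p = 0.0556), Hexa without CON 2, 3, 4 or 5 or C10 1, 2, 4, 5 or 6 (adjusted p = 0.0589 to 0.112), Neurod1 without CON 2, 3, 4 or 5 or C10 4, 5 or 6 (adjusted p = 0.0529 to 0.061), Thegl without CON 1, 2, 3, 4 or 5 or C10 2, 3, 4, 5 or 6 (adjusted p = 0.0534 to 0.112), Nr1d2 without CON 2, 3, 4, 5 or 6 or C10 1, 2, 3, 4, 5 or 6 (adjusted p = 0.0507 to 0.134), Alas1 without CON 1, 2, 3, 4, 5 or 6, CRS 3 or C10 2, 4, 5 or 6 (adjusted p = 0.0534 to 0.134) and Il33 without CON 2, 3, 4 or 5 or C10 1, 3, 4, 5 or 6 (adjusted p = 0.0697 to 0.116). The number of genes called was 8, 10, 9 and 12 without CON 2, 3, 4 and 5, 110 without CRS 1, and 16, 14, 19, 3, 6 and 11 without C10 1 to 6. With the 2 groups alone 46 were higher and 115 lower, with the olfactory covariate 142 and 160, by DESeq2 120 and 198, by limma-voom 97 and 155, and with no filter on low counts 2 and 15. Dbp overlaps Sphk2 on the other strand (15294 and 15792 counts in all) and Neurod1 overlaps Cerkl (1158 and 1134), so without strand both values are uncertain. In mm10 the files place Dbp (ENSMUSG00000059824) on chromosome 7 from 45705088 to 45710203 and Ctsd (ENSMUSG00000007891) on chromosome 7 from 142375911 to 142388038.

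**Figure D2:**
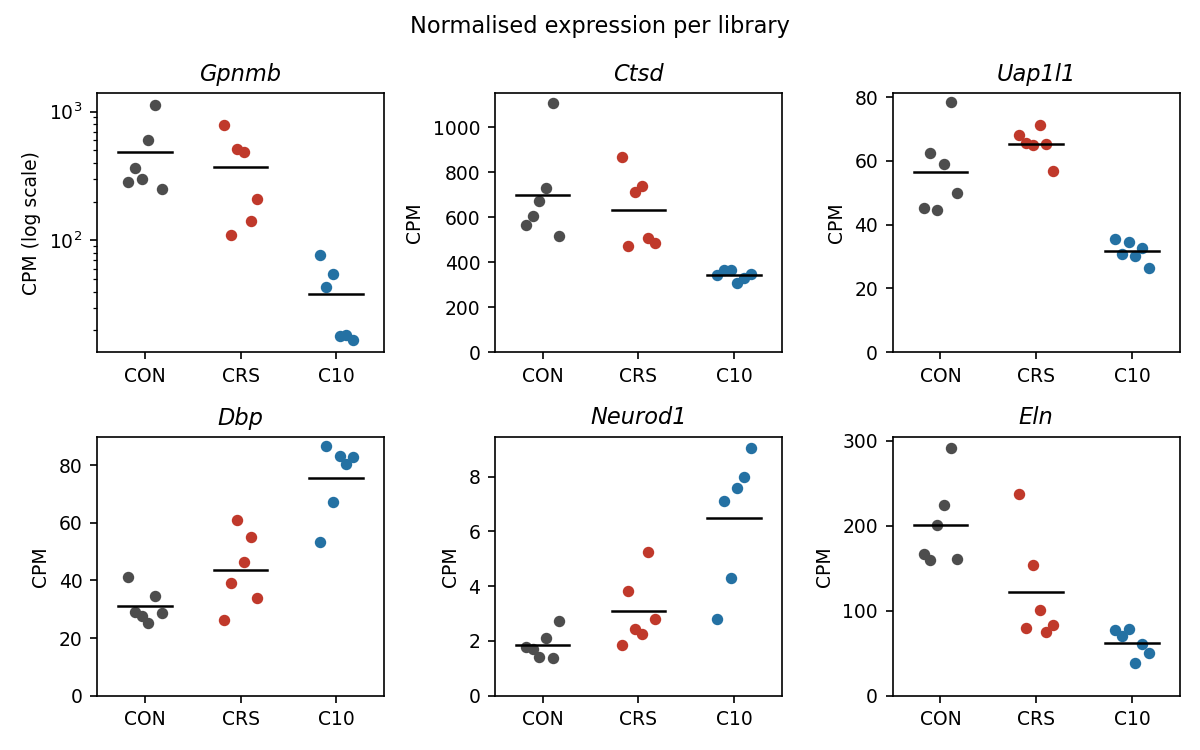
Normalised expression (CPM) of 6 genes in each of the 18 libraries; points are libraries, the line is the group mean, and the axis of Gpnmb is logarithmic. Gpnmb averaged 38.1 CPM in C10 and Dbp 75.6 CPM.

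Clock and olfactory genes stood higher in C10 than in CON. Clock genes rose as a group, with 10 of 14 measured members above 0 (median log2 fold change 0.48, camera adjusted p = 6.96e-05, and adjusted p = 0.334 with an estimated correlation). Dbp (1.29 ± 0.18), Nr1d2 (0.52 ± 0.10) and Per2 (0.54 ± 0.12) had the smallest p in that direction. Of these 14 genes, 10 rose and 3 fell when adjusted over the list alone, against 2 and 1 over all genes tested. By fry the list passed as well (adjusted p = 0.0148); the member that fell over all genes, Arntl (-0.76 ± 0.14), is the activator that peaks opposite to Dbp, and was picked out after its value was seen. Immature olfactory neuron and progenitor genes rose as a group, with 11 of 11 measured members above 0 (median log2 fold change 0.95, camera adjusted p = 8.75e-09, and adjusted p = 0.334 with an estimated correlation). Neurod1 (1.80 ± 0.30) and Neurog1 (1.73 ± 0.41) were among those of smallest p in that direction. Of these 11 genes, 7 rose when adjusted over the list alone, against 1 over all genes tested. Receptors for odorants rose as a group, with 570 of 635 measured members above 0 (median log2 fold change 0.51, camera adjusted p = 2.2e-20, and adjusted p = 0.363 with an estimated correlation). Olfr1167 (1.60 ± 0.30), Olfr211 (1.58 ± 0.38) and Olfr948 (1.82 ± 0.46) had the smallest p in that direction. Of these 635 genes, 1 rose when adjusted over the list alone, against 1 over all genes tested. Genes of sustentacular cells and Bowman glands, which support the olfactory neurons, rose as a group, with 8 of 9 measured members above 0 (median log2 fold change 0.28, camera adjusted p = 0.0473, and adjusted p = 0.661 with an estimated correlation). Cbr2 (0.30 ± 0.11), Cyp2a5 (0.44 ± 0.20) and Sec14l3 (0.36 ± 0.22) had the smallest p in that direction. Of these 9 genes, 0 passed, adjusted over the list alone or over all genes tested. Tuft cell markers rose as a group, with 6 of 9 measured members above 0 (median log2 fold change 0.19, camera adjusted p = 0.0384, and adjusted p = 0.334 with an estimated correlation). Gnat3 (1.26 ± 0.32), Dclk1 (0.19 ± 0.08) and Avil (0.39 ± 0.18) had the smallest p in that direction. Of these 9 genes, 1 rose when adjusted over the list alone, against 0 over all genes tested. Avil overlaps Tsfm, and odorant receptors have near-identical copies, so both are uncertain. With the olfactory covariate the camera adjusted p of the sustentacular list was 0.151. The camera call ended when 1 library was left out for sustentacular cells and Bowman glands without CON 3, 4 or 5, CRS 3 or C10 2, 4, 5 or 6 (adjusted p = 0.0518 to 0.125) and tuft cells without CON 1 or C10 1 or 2 (adjusted p = 0.0676 to 0.121). Alternatives moved the median by over 1.5 times, the camera call kept, for odorant receptors (0.31 with the olfactory covariate) and tuft cells (0.10 without C10 5). The edgeR call of Olfr1167 ended with no filter on low counts (adjusted p = 0.0596), and it ended without CON 1, 2, 3, 4, 5 or 6, CRS 3 or 6 or C10 1, 2, 4, 5 or 6 (adjusted p = 0.0501 to 0.112). By limma on log2 of FPKM plus 1 the log2 fold change of Olfr1167 was 0.52, the call kept (limma adjusted p = 0.0374). In CRS against CON the immature olfactory list also lay above 0 in 10 of 11 members (median 0.40, camera adjusted p = 0.0519). It passed there with the strict filter, the replicate block and without CON 1 or 6, CRS 1, 3 or 4 or C10 1 or 3 (camera adjusted p = 0.00784 to 0.0493). The tuft list had a median of 0.19 there (camera adjusted p = 0.0677). It passed with the strict filter, without CRS 5 and without CRS 2 and 5 together (camera adjusted p = 0.0343 to 0.0402).

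Connective tissue and vessel genes stood lower in C10 than in CON. Matrix remodelling genes fell as a group, with 20 of 20 measured members below 0 (median log2 fold change -0.75, camera adjusted p = 5.52e-11, and adjusted p = 0.334 with an estimated correlation). Thbs1 (-1.04 ± 0.27), Acta2 (-0.53 ± 0.15) and Mmp2 (-0.75 ± 0.22) had the smallest p in that direction. Of these 20 genes, 14 fell when adjusted over the list alone, against 0 over all genes tested. Markers of fibroblasts fell as a group, with 8 of 8 measured members below 0 (median log2 fold change -0.74, camera adjusted p = 2.97e-06, and adjusted p = 0.334 with an estimated correlation). Col6a2 (-1.005 ± 0.24), Col6a1 (-0.80 ± 0.23) and Dcn (-0.59 ± 0.17) had the smallest p in that direction. Of these 8 genes, 7 fell when adjusted over the list alone, against 0 over all genes tested. Markers of endothelium fell as a group, with 11 of 11 measured members below 0 (median log2 fold change -0.54, camera adjusted p = 7.13e-06, and adjusted p = 0.355 with an estimated correlation). Esam (-0.42 ± 0.13), Tie1 (-0.65 ± 0.22) and Tek (-0.54 ± 0.20) had the smallest p in that direction. Of these 11 genes, 5 fell when adjusted over the list alone, against 0 over all genes tested. Bone and cartilage genes, from tissue under the mucosa, fell as a group, with 15 of 16 measured members below 0 (median log2 fold change -0.98, camera adjusted p = 0.00577, and adjusted p = 0.564 with an estimated correlation). Ctsk (-0.77 ± 0.30), Ibsp (-1.68 ± 0.70) and Matn1 (-3.15 ± 1.31) had the smallest p in that direction. Of these 16 genes, 0 passed, adjusted over the list alone or over all genes tested. Genes of red blood cells fell as a group, with 7 of 7 measured members below 0 (median log2 fold change -1.04, camera adjusted p = 0.00978, and adjusted p = 0.559 with an estimated correlation). Alas2 (-1.18 ± 0.48), Hba-a1 (-1.09 ± 0.50) and Hba-a2 (-1.04 ± 0.51) had the smallest p in that direction. Of these 7 genes, 0 passed, adjusted over the list alone or over all genes tested. Squamous and basal keratinocyte genes fell as a group, with 16 of 16 measured members below 0 (median log2 fold change -0.63, camera adjusted p = 0.000257, and adjusted p = 0.361 with an estimated correlation). Krt13 (-2.26 ± 0.66), Krt4 (-1.08 ± 0.32) and Krt15 (-0.59 ± 0.21) had the smallest p in that direction. Of these 16 genes, 2 fell when adjusted over the list alone, against 0 over all genes tested. The camera adjusted p of the red blood cell list was 0.0551 with the olfactory covariate. The camera call ended without 1 library for bone and cartilage without CON 3 (adjusted p = 0.175) and erythroid cells without CON 3 (adjusted p = 0.0559). Alternatives moved the median by over 1.5 times, the camera call kept, for endothelium (-0.33 with the olfactory covariate), bone and cartilage (-0.56 with the olfactory covariate) and squamous and basal keratinocyte (-0.32 without CON 3).

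7 more lists, of macrophages, inflammation, stress and metabolism, also stood lower in C10 than in CON. Handling-sensitive immediate early and heat shock genes fell as a group, with 16 of 16 measured members below 0 (median log2 fold change -0.59, camera adjusted p = 5.63e-09, and adjusted p = 0.334 with an estimated correlation). Hspa1b (-0.85 ± 0.13), Hspa1a (-0.62 ± 0.10) and Nr4a1 (-1.08 ± 0.28) had the smallest p in that direction. Of these 16 genes, 5 fell when adjusted over the list alone, against 2 over all genes tested. Macrophage and dendritic cell markers fell as a group, with 14 of 14 measured members below 0 (median log2 fold change -0.68, camera adjusted p = 0.000101, and adjusted p = 0.491 with an estimated correlation). Cd68 (-1.502 ± 0.39), C1qc (-0.90 ± 0.35) and C1qb (-0.96 ± 0.39) had the smallest p in that direction. Of these 14 genes, 1 fell when adjusted over the list alone, against 0 over all genes tested. NF-kB and acute inflammation genes fell as a group, with 20 of 22 measured members below 0 (median log2 fold change -0.60, camera adjusted p = 0.00728, and adjusted p = 0.74 with an estimated correlation). Il6 (-2.74 ± 0.78), Ptgs2 (-1.45 ± 0.50) and Cxcl1 (-1.19 ± 0.42) had the smallest p in that direction. Of these 22 genes, 0 passed, adjusted over the list alone or over all genes tested. Producers of reactive oxygen fell as a group, with 11 of 12 measured members below 0 (median log2 fold change -0.55, camera adjusted p = 0.00642, and adjusted p = 0.559 with an estimated correlation). Duox1 (-0.87 ± 0.23), Nox4 (-0.91 ± 0.29) and Duoxa1 (-0.67 ± 0.27) had the smallest p in that direction. Of these 12 genes, 2 fell when adjusted over the list alone, against 0 over all genes tested. Hypoxia and glycolysis genes fell as a group, with 16 of 18 measured members below 0 (median log2 fold change -0.16, camera adjusted p = 0.00888, and adjusted p = 0.361 with an estimated correlation). P4ha1 (-0.21 ± 0.07), Adm (-0.70 ± 0.27) and Pgk1 (-0.20 ± 0.09) had the smallest p in that direction. Of these 18 genes, 0 passed, adjusted over the list alone or over all genes tested. Glucocorticoid response genes fell as a group, with 7 of 9 measured members below 0 (median log2 fold change -0.14, camera adjusted p = 0.0204, and adjusted p = 0.355 with an estimated correlation). Errfi1 (-0.56 ± 0.14), Sgk1 (-0.40 ± 0.16) and Klf9 (-0.31 ± 0.14) had the smallest p in that direction. Of these 9 genes, 1 fell when adjusted over the list alone, against 0 over all genes tested. Genes of APE1 redox targets and partners fell as a group, with 11 of 14 measured members below 0 (median log2 fold change -0.17, camera adjusted p = 0.0249, and adjusted p = 0.491 with an estimated correlation). Egr1 (-0.82 ± 0.29), Rela (-0.27 ± 0.12) and Fos (-0.74 ± 0.38) had the smallest p in that direction. Of these 14 genes, 0 passed, adjusted over the list alone or over all genes tested. In C10 against CRS this APE1 list had 8 of 14 members below 0 and did not pass (median -0.07, camera adjusted p = 0.38). It passed there as lower without CRS 2 and 5 together (median -0.20, camera adjusted p = 0.0424). In CRS against CON it had 9 of 14 below 0 and did not pass (median -0.085, camera adjusted p = 0.293). With the olfactory covariate the camera adjusted p of the APE1 list in C10 against CON was 0.0969, that of NF-kB 0.196, that of the NADPH oxidases 0.0568 and that of the glucocorticoid response 0.0551. Leaving out 1 library ended the camera call of NF-kB and acute inflammation without CON 3 (adjusted p = 0.131) and APE1 redox targets and partners without CON 3 or 4 (adjusted p = 0.0522 to 0.06). Alternatives moved the median by over 1.5 times, the camera call kept, for macrophages and dendritic cells (-0.43 with the olfactory covariate), NF-kB and acute inflammation (-0.30 with the replicate block) and NADPH oxidases and ROS production (-0.32 without CON 3). By edgeR the call ended for Hspa1a without CON 2, 3 or 4 or C10 4 or 5 (adjusted p = 0.0529 to 0.0588) and Hspa1b without C10 4 (adjusted p = 0.0556). The fixed genes Il4 (-0.18 ± 0.24), Tnf (-0.71 ± 0.41), Il1b (-0.72 ± 0.55), Muc5ac (0.92 ± 0.43) and Chil4 (5.24 ± 1.40) did not pass (edgeR adjusted p from 0.138 to 0.788).

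**Figure D3:**
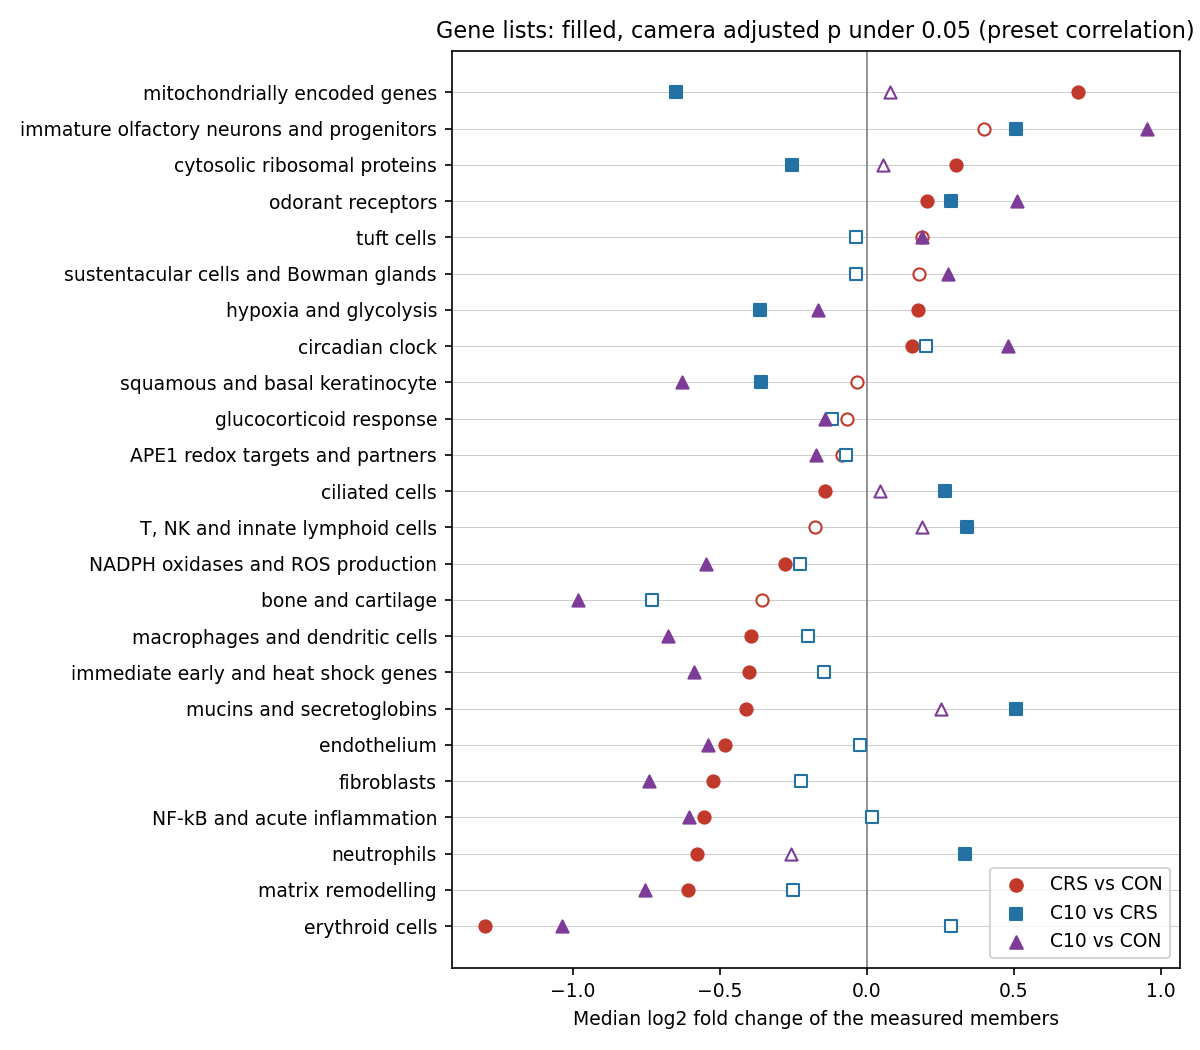
Median log2 fold change of each gene list that passed in at least 1 comparison, by comparison; a filled marker has a camera adjusted p under 0.05 at the preset correlation. With an estimated correlation 0 of the 43 lists passed in any comparison, and by fry 0, 1 and 1.

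Across the 43 lists tested in each comparison, camera with the preset correlation called 5 higher and 11 lower in CRS against CON, 6 and 4 in C10 against CRS, and 5 and 13 in C10 against CON. With an estimated correlation camera called 0 in each, where the smallest adjusted p was 0.559, 0.297 and 0.334. By fry, which asks whether a list's genes moved on balance 1 way, 0, 1 and 1 passed. Without CRS 1, fry also passed the endothelium, fibroblast and mitochondrially encoded lists (fry adjusted p = 0.0103 each) and the circadian clock (fry adjusted p = 0.0293) in CRS against CON. In that fit the smallest camera adjusted p with an estimated correlation was 0.585.

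Apex1, which encodes APE1, was measured at low counts. It averaged 6.16 ± 1.06 CPM in CON, 5.92 ± 0.669 in CRS and 5.11 ± 0.939 in C10 (SD, n = 6 each), and no difference passed: -0.06 ± 0.15 for CRS against CON (edgeR adjusted p = 0.89), -0.21 ± 0.15 for C10 against CRS (edgeR adjusted p = 0.568) and -0.27 ± 0.15 for C10 against CON (edgeR adjusted p = 0.444). Without CON 4 the CRS value was 0.02, and by limma-voom 0.05. Apex1 (ENSMUSG00000035960) overlaps Pip4p1 on the other strand, which had 13254 counts in all against 1766 for Apex1, so its level is uncertain without strand; the amount of mRNA says nothing of the activity of the protein.

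Whether the compound moved genes back toward control levels was asked by setting the log2 fold changes of C10 against CRS beside those of CRS against CON. Across 18291 genes, which are not independent, r was -0.42 and the covariance -0.043. Both comparisons share the CRS libraries, and groups simulated as unchanged gave r = -0.50 (20 runs, -0.52 to -0.48) and a covariance of -0.037 (-0.039 to -0.035), so r lay above and the covariance below all 20 runs. Of 100 relabellings of the libraries, 81 gave an r as low and 38 a covariance as low, and with the CRS libraries split 3 and 3 between the comparisons the mean r of 20 splits was 0.02, from -0.26 to 0.42, with 9 below 0. Ppargc1a was the 1 gene called in both comparisons, rising in CRS against CON and falling in C10 against CRS; the shared CRS libraries favour such a double call without any return toward control, and no expected number was computed under that sharing. Gpnmb, Il33, Uap1l1 and Dpp7 were called in C10 against both CRS and CON, all 4 with the same sign, which the shared C10 libraries favour.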

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

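The tests of CRS 1 were chosen after the counts without each library had been seen, and the test with the olfactory covariate after its own value had been seen. In groups of 6, a library was picked out where its gap to the nearest other exceeded Dixon's 95% limit relative to the range. This happened in 29 of 534 groups, where chance alone gives about 27.

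Most such values were in CRS libraries. CRS 1 had a Pdgfrb of 140 CPM, against 56.6 to 76.7 in the other CRS libraries, and a Thbs1 of 461 CPM, against 147 to 217. Its mean log2 level of nasal gland genes was 8.64, against 11.22 to 12.57. CRS 2 had a Cxcl1 of 0.557 CPM, against 3.33 to 7.27, a Nkg7 of 0.186 CPM, against 1.45 to 3.95, and a Tnf of 1.42 CPM, against 5.44 to 9.54. The same library had a mean log2 interferon level of 2.44, against 4.44 to 4.88, 12 counts of Il13, against 0 to 1, and 36 of Clca1, against 0 to 9. CRS 3 had a Matn1 of 0.0644 CPM, against 3.71 to 9.73, and an Olfr1320 of 0.322 CPM, against 0.928 to 1.42. CRS 4 had a Cd63 of 452 CPM, against 286 to 335, and an Rps28 of 270 CPM, against 57 to 83.2. CRS 5 had a Per2 of 46.8 CPM, against 27 to 32.6, and 24 counts of Il25, against 0 to 7. CRS 6 had 8 counts of Il5, against 0 to 2.

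In the other groups CON 3 had a Galnt15 of 36.5 CPM, against 28.2 to 30.8, a Krt13 of 25.7, against 1.65 to 4.06, a Krt4 of 47.1, against 11.1 to 18.2, and a mean log2 level of NRF2 genes of 7.11, against 6.9 to 6.97. CON 4 had 1 count of Il13, against 0 in the others, and CON 5 had 59 of Epx, against 0, with a mean log2 level of skeletal muscle genes of 2.19, against -0.73 to 0.03. C10 1 had 21 counts of Epx, against 0 to 2, and a mean log2 level of hypoxia and glycolysis genes of 5.73, against 5.84 to 5.89. C10 2 had an Il33 of 113 CPM, against 127 to 133, and a Thbs1 of 231 CPM, against 138 to 159. C10 3 had a Rela of 79.9 CPM, against 60.6 to 66.6, and C10 4 had 219 counts of Clca1, against 1 to 21.

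Without CRS 1, 994 genes were called between CRS and CON in place of 1. Adding to the fit of all libraries the mean level of gland genes (4 genes called) did not bring these calls back. The mean level of olfactory neuron genes (2 called) did not bring them back either. Yet a regrouping that exchanged CRS 1 with CON 6 called 1083 genes, and 0 with the olfactory covariate. The share of olfactory tissue in CRS 1 therefore stays open. Since the same kind of test left that share open, it cannot decide on gland tissue in CRS 1 either. On the line from the CON mean (0) to the mean of the other CRS libraries (1) over the 994 genes, CRS 1 lay at -0.11, within CON (-0.20 to 0.27) and below the other CRS libraries (0.66 to 1.34), and its Chil4 of 17.4 CPM was below the CON maximum of 22.0 CPM, which is CON 6 alone, and above the 0.176 to 3.1 CPM of the other 5 CON libraries. This position in part restates that CRS 1 was picked because leaving it out raised the count. A wrong label may account for CRS 1, and so may a mouse that did not respond to papain; both stay open, and the second was not tested. Its 10 most counted genes held 6.78% of the counts, the lowest share of the 18 libraries (the next was 7.02%), so its counts were not gathered in few genes, while a lack of counts from abundant genes stays open.

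Splits of the 12 libraries of a comparison into other groups of 6 show how far chance can be excluded. For CRS against CON, 4 of 100 splits, the real one included, gave as many genes as the real 1, and the highest of the others, which exchanged CRS 1 with CON 6, gave 1083. The real count was 0 with the 2 groups alone and without CON 1, 4 or 5 or CRS 4 or 6, so these splits do not exclude chance for it. For C10 against CRS, 5 of 100 splits gave as many as the real 15, so chance cannot be excluded, and the highest other gave 2513. For C10 against CON, 1 of 100 gave as many as the real 29, the smallest share that 100 splits can show, and the highest other gave 1. This argues against chance without excluding it, and the real count was 3 without C10 4 and 6 without C10 5. With the olfactory covariate the splits as large were 4 of 100 for CRS against CON (real 2, highest other 1143), 3 for C10 against CRS (real 662, highest other 1584) and 1 for C10 against CON (real 302, highest other 34). Splits that call far more genes than the real one point to a structure of the libraries other than the groups.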

How the results depend on the processing

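The fits without CRS 2 and 5 were chosen after the data had been seen. Counts of called genes moved with the tool, with the olfactory covariate and with single libraries, and the cause was not tested. Under RLE factors all 177 named gene results kept their side of the threshold, and with the olfactory covariate 152 did and 25 passed that had not. Depth limits Il5, Il13, Il25 and Tslp, which had few counts.

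Genes higher in CRS than in CON numbered 0 with a 2-fold minimum, 3 with the strict filter, 0 with the replicate block, 2 with the olfactory covariate, 0 with the 2 groups alone, 129 by DESeq2, 395 by limma-voom and 2 by limma on either FPKM scale; genes lower were 50 by DESeq2 and 545 by limma-voom. Leaving out 1 library gave 0 to 398 higher and 0 to 596 lower. Genes higher in C10 than in CRS were 0 with a 2-fold minimum, 5 with the strict filter, 387 with the olfactory covariate, 109 by DESeq2, 227 by limma-voom, 5 by limma on log2 of FPKM plus 1 and 37 without CRS 2 and 5; lower were 2, 275 with the covariate, 7 with the 2 groups alone, 241 by DESeq2, 321 by limma-voom and 63 without CRS 2 and 5. Leaving out 1 library gave 3 to 24 higher and 4 to 57 lower. Genes higher in C10 than in CON were 3 with a 2-fold minimum, 2 with no filter, 2 with the replicate block, 142 with the covariate, 46 with the 2 groups alone, 120 by DESeq2, 97 by limma-voom and 30 without CRS 2 and 5; lower were 7, 10 with the block, 160 with the covariate, 115 with the 2 groups alone, 198 by DESeq2, 155 by limma-voom and 44 without CRS 2 and 5. Leaving out 1 library gave 1 to 23 higher and 2 to 87 lower.

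With an estimated correlation 0 were called in each comparison and direction. Without CRS 2 and 5, 7 were lower in CRS than in CON and 14 lower in C10 than in CRS; with the olfactory covariate 9 were higher and 8 lower in C10 than in CON. Leaving out 1 library gave 4 to 8 higher and 8 to 14 lower in CRS against CON, 4 to 8 and 4 to 6 in C10 against CRS, and 4 to 7 and 9 to 15 in C10 against CON. Of the 44 list calls, the olfactory covariate ended 9 and the fits without CRS 2 and 5 ended 7 and turned 3.

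Some values changed sign. Apex1 in CRS against CON was 0.05 by limma-voom and 0.02 without CON 4, from -0.11 to 0.02 over single libraries left out, and its values in C10 against CRS (-0.29 to -0.16) and C10 against CON (-0.35 to -0.19) kept their sign. Il4 in CRS against CON was 0.042, 0.003 and 0.031 without CON 6, CRS 1 and CRS 4, and from -0.31 (without CRS 5) to 0.042 over all libraries left out. In C10 against CRS Il4 was from -0.21 (without CRS 4) to 0.13 without CRS 5 and 0.22 without CRS 2 and 5. Without CRS 2 and 5, Chil4 was 0.54, S100a9 -0.16, Tnf -0.24 and Trac -0.013 in C10 against CRS, and the medians of neutrophils and of T, NK and innate lymphoid cells were -0.18 and -0.12; the odorant receptors in CRS against CON were -0.064. Il6 in C10 against CRS was 1.13 by limma-voom, and Tnf was -0.16 without CRS 2, -0.05 without C10 1 and -0.06 without C10 2, with 0.23 without CRS 1 as its highest. The correlation of C10 against CRS with CRS against CON went from -0.42 to 0.017 when the CRS libraries were split. It could not be computed over genes called in CRS against CON, since that was 1 gene.

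The replicate numbers share only a number: the 18 same-numbered pairs correlated from -0.57 to 0.52 and 8 exceeded 0.1, and 5 of 18 libraries correlated best with their own number. With the replicate block, 13 of the 177 named gene results no longer passed. In C10 against CON these were Alas1, Ctsd, Hexa, Il33, Nkain1, Nr1d2, Olfr1167, Thegl and Trem2 (edgeR adjusted p = 0.076 to 0.134). The others were Cd63, Gpnmb and Ppargc1a in C10 against CRS (edgeR adjusted p = 0.0502 to 0.0772) and Ppargc1a in CRS against CON (edgeR adjusted p = 0.0692). The 44 list calls were kept, and lists were added: 6 in place of 5 were higher in CRS than in CON, 6 in place of 5 higher and 14 in place of 13 lower in C10 than in CON.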

Other observations

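The list of lysosome genes, the list of MiT/TFE targets and the test of antiphase among clock genes were chosen after the called genes had been seen. Among lists not yet described, the mature olfactory neuron genes lay above 0 in 12 of 12 members in both CRS and C10 against CON (median log2 fold changes 0.21 and 0.23), and camera did not call them (adjusted p = 0.0991 and 0.0684). Genes of B and plasma cells had medians of 0.37 and 0.70 in the same comparisons (camera adjusted p = 0.793 and 0.268), and the interferon response 0.05 and 0.23 (camera adjusted p = 0.793 and 0.243). Mast cell and basophil markers lay below 0 in 6 of 7 members in CRS against CON (median -0.55; camera adjusted p = 0.0664). The 24 NRF2 and antioxidant genes had medians of 0.05 in CRS and 0.09 in C10 against CON (camera adjusted p = 0.527 and 0.056), and the 21 genes of base excision repair, the pathway of APE1, 0.01 and -0.03 (camera adjusted p = 0.584 and 0.764). Genes of T, NK and innate lymphoid cells lay above 0 in 11 of 15 members in C10 against CON (median 0.19; camera adjusted p = 0.818). Other fits did call some of these lists. Cell cycle genes, which no main fit called, passed as lower in C10 against CON without CON 1, 2 or 6 (camera adjusted p = 0.00913 to 0.0179). They also passed there without CRS 1, 2 or 6 (camera adjusted p = 0.0352 to 0.04885) and without C10 1, 3 or 6 (camera adjusted p = 0.0225 to 0.03535). In CRS against CON they passed as lower without CRS 1 (camera adjusted p = 0.0122). The T, NK and innate lymphoid list passed as higher in C10 against CON with the olfactory covariate (camera adjusted p = 0.0207). In CRS against CON 14 of its 15 members lay below 0 (median -0.18, camera adjusted p = 0.0605). There it passed as lower without CON 1, 2 or 3 or CRS 1, 3 or 4 (camera adjusted p = 0.00665 to 0.0393). Mature olfactory neurons passed in CRS against CON without CON 1 or 6 or CRS 1, 3 or 4 (camera adjusted p = 0.0179 to 0.0494), and in C10 against CON without CON 1, 2 or 6 or C10 1 or 3 (camera adjusted p = 0.0111 to 0.0378). Interferon genes passed in CRS against CON without CRS 2 (camera adjusted p = 0.0158) and without CRS 2 and 5 together (camera adjusted p = 0.00518), and in C10 against CON without CON 4 or C10 6 (camera adjusted p = 0.0182 to 0.0469) and with the olfactory covariate (camera adjusted p = 0.014). B and plasma cell genes passed in CRS against CON without CRS 2 and 5 together (camera adjusted p = 4.21e-05), and in C10 against CON without C10 4 (camera adjusted p = 0.0434) and with the olfactory covariate (camera adjusted p = 0.00341). Mast cell and basophil markers passed in CRS against CON without CRS 4 (camera adjusted p = 0.0267), and NRF2 genes in C10 against CON without CON 2 or 3, CRS 4 or C10 4 or 6 (camera adjusted p = 0.0263 to 0.0477), with the strict filter (camera adjusted p = 0.0476) and with the olfactory covariate (camera adjusted p = 0.0409).

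Type 2 cytokines and receptors lay below 0 in 10 of 14 measured members in CRS against CON (median -0.18, camera adjusted p = 0.0664). They passed as lower without CON 1 or 2 or CRS 1 or 4 (camera adjusted p = 0.0133 to 0.0468). In C10 against CRS they passed as higher without CRS 1 (camera adjusted p = 0.037). The type 2 airway response list of 18 measured genes did not pass in any of the 3 comparisons (camera adjusted p = 0.758, 0.529 and 0.152), and in C10 against CON it passed without CON 3 (camera adjusted p = 0.024) and without CRS 2 and 5 together (camera adjusted p = 0.0372). Adjusted over the list alone 1 member rose in CRS against CON, 3 rose and 1 fell in C10 against CRS, and 4 rose and 2 fell in C10 against CON, against 0, 1 and 0 called over all genes tested. Skeletal muscle genes lay below 0 in 7 of 7 members in CRS and in C10 against CON (medians -0.74 and -0.70), and camera did not call them (adjusted p = 0.252 and 0.145). Matrix remodelling did not pass in C10 against CRS (median -0.25, camera adjusted p = 0.0925). It passed there as lower with the olfactory covariate and without CRS 2 or 5 or C10 1, 2 or 3 (camera adjusted p = 0.00807 to 0.0378). Bone and cartilage passed there as lower without CON 3, CRS 3 or C10 1, 2 or 3 (camera adjusted p = 0.00824 to 0.0493). Without CRS 2 and 5 together both passed (camera adjusted p = 0.000415 and 0.0152).

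Lysosome genes were lower in C10 than in CRS: of 55 listed, 54 lay below 0 (median -0.31), 4 of them called, and the camera p with an estimated correlation was 0.00218, which is not independent evidence because the list was written with called genes in it. The mean level differed by -0.32, and permutation p-values of this list carry the same limit. After regressing out the level of macrophage genes the difference was -0.30 (exact permutation p = 0.00217, the smallest that 924 splits allow). After olfactory genes it was -0.31 (exact permutation p = 0.00217) and after bone and cartilage genes -0.21 (exact permutation p = 0.0108). Between C10 and CRS the macrophage level itself differed by -0.094 (exact permutation p = 0.80). The olfactory level differed by 0.032 (exact permutation p = 0.90). Regressing these levels out could therefore change little. Without CRS 2 and 5 the macrophage and dendritic cell list was lower in C10 than in CRS (median -0.54, camera adjusted p = 0.00591). In that fit the mature olfactory neuron list was higher (median 0.33, camera adjusted p = 0.0313). The small differences thus depend on these libraries, and the share of either tissue stays open. A subset of macrophages was not tested. The bone and cartilage level differed by -0.707 (exact permutation p = 0.119). The bone and cartilage list passed as lower in C10 than in CRS in some fits, as without C10 2 (median -0.75, camera adjusted p = 0.00824). The -0.21 left cannot decide on bone tissue, because the lysosome list was written with called genes in it. Bone tissue as a cause, whole or in part, stays open. A candidate explanation is lower activity of the MiT/TFE factors, which drive lysosome genes, under the compound. A list of 15 of their targets outside the lysosome had a median of -0.24 (camera p = 3.94e-05 with an estimated correlation), but it too was written after its members had been seen, so the cause stays open.

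Clock genes differed between C10 and CON. Of 13 members, 12 moved as their antiphase predicts, Dbp, Nr1d2 and others up with Arntl, Npas2 and Clock down, and the antiphase score rose by 1.14 (exact permutation p = 0.00217; adjusted p = 0.0065 over 3 comparisons). It differed by 0.52 in CRS against CON (13 of 13 members, exact permutation p = 0.0346) and by 0.61 in C10 against CRS (11 of 13 members, exact permutation p = 0.0173). The score holds Dbp, Nr1d2 and Arntl and was chosen after these had been called between C10 and CON. Its p-values are therefore not independent evidence. After regressing out olfactory neuron genes the difference between C10 and CON was 0.93 (exact permutation p = 0.00433, with the same limit), which argues against the share of olfactory tissue as the whole cause. Collection at another hour may account for the pattern, since it moves the members in antiphase, and the labels give no hour; an effect of the treatment on the clock also stays open and was not tested.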
